A study of Homo sapiens with 28 samples.

How the data were processed

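The series holds 28 samples of HEK293T cells: 12 RNA-seq libraries (untreated, VPA, ASO1 and VPA+ASO1, 3 libraries each), 4 POINT-seq samples and 12 ChIP-seq samples. The POINT-seq and ChIP-seq samples were not analysed here. Per the labels the RNA-seq libraries were made from total RNA of embryonic kidney cells. The deposited table gives estimated counts of reads for 63216 Ensembl gene IDs in 12 columns, not divided by library size or gene length. From 17387 to 20438 values per column carry fractions. The authors list Trim Galore 0.4.4, BWA 0.7.15-r1140, SAMtools 1.11, Picard and bedtools and the builds GRCh38, hg38 and dm6 for the whole series, with no role for each; the tool that counted reads per gene, its annotation and its strand setting are not given in the sources used here. Gene symbols were matched by Ensembl ID to a reference list of gene names. It gave a symbol to 56690 of the IDs and none to 6526, the latter with 2 to 2.25% of the counts of each library. Coordinates come from a RefSeq annotation of GRCh38, joined by symbol.

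Totals ran from 21510444 counts (untreated replicate 1) to 60614968 (ASO1 replicate 1), and 20381 to 23752 genes had at least 5 counts in a library. No unique molecular identifiers are given, so counts are not independent molecules. Libraries of one group were not copies of each other: chi-square per degree of freedom between replicates was 47.7 to 331.9 over genes with at least 20 counts in the pair.

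Expected counts were rounded and analysed in R 4.3.3. The main test was edgeR 4.0.16 (glmQLFit with robust settings and glmQLFTest, TMM factors, filterByExpr with default settings, 21484 genes tested), with all 12 libraries in one fit of 4 groups and no block, 8 residual degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05 over all genes. This test, the comparisons, 39 gene lists, the rule for named genes and a set of alternatives were chosen before the data were examined. The alternatives were DESeq2-type and upper-quartile factors, no filter, at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma voom (limma 3.58.1), the compared groups alone, replicate number as a block (6 residual degrees of freedom), an absolute log2 fold change of at least 1, and each library left out in turn. Lists were tested with camera (limma) at a preset correlation of 0.01, over the lists with at least 3 tested members, and also with an estimated correlation and with fry; 897 of their 898 members matched the table.

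The rule for named genes took SMN1 and SMN2, then for each treatment against untreated the 7 highest and 7 lowest genes by log2 fold change among those called, with average log2 CPM of at least 3, no overlap between the replicates of both groups and a known symbol, plus up to 2 higher and 2 lower members of each list; 4 and 4 for VPA+ASO1 against ASO1; and for the interaction, where none passed, the 3 with the smallest p. Since the main test called no gene, the rule was applied to the fit with the replicate block, a choice made after the counts were seen; of the list members those with the largest adjusted p were left out for room. Genes outside the rule are named as such, and 2 results that the rule gave are not reported here.

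Further alternatives were added after the data were seen: leaving out replicate 1 of every group, with and without the block; the block with the other scaling factors or with the 2-fold requirement; a replicate effect of its own in cells with and without VPA; and a VPA effect of its own in replicate 1. Leaving out replicate 1 keeps 2 libraries per group. Gene families were formed after the data were seen from the letters of the symbol before its first digit, with at least 8 tested members, 297 in all. Labels were permuted over all 10 splits of each 3 against 3 comparison, over 4 within-number swaps for the blocked fits, and over 100 random draws for the interaction. Other tests used 1000 bootstrap draws and libraries thinned to the smallest total.

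The tests were tried on simulated data of 21484 genes, 200 of them changed, with the spread between replicates of these libraries. For VPA against untreated the unblocked edgeR test recovered 28.8% of genes changed 4-fold and 1.5% of those changed 2-fold, and the blocked test 50% and 17.9%. The blocked test made 52 calls, 7 of them false, and DESeq2 made 90 calls, 40 of them false. With a replicate effect of its own in cells with and without VPA, the ASO1 test recovered 62.7% of genes changed 2-fold and 46.3% of those changed 1.5-fold, with 7 false among 131 calls. The other ASO1 fits were weaker: 0% of genes changed 2-fold were recovered with no block and 19.4% with the replicate block. For the interaction with the block it was 1.5%. The camera test called the 1 changed list and 0 of the other 38. The simulation matched the spread of these libraries, not the correlation between genes of a list. Its libraries were drawn independently, with no level shared by a replicate number in the unblocked tests. Of the above, only that with a replicate effect of its own in cells with and without VPA held VPA responses differing by number. Recoveries and false calls of the other tests may thus differ in the real libraries. Nor does the simulation show how often camera makes false calls in them. In the real libraries, other splits of the VPA and untreated libraries gave up to 18 lists, and an estimated correlation gave 0 with the real labels. Those splits keep part of the VPA difference and some mix replicate numbers, so their lists need not be false calls.

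Figures were drawn with matplotlib from the values of the tables. GC content was not tested, as no genome sequence was used here.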

Results

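RNA was sequenced from HEK293T cells, an established human embryonic kidney line, in 4 groups of 3 libraries: untreated, treated with valproic acid (VPA), treated with the antisense oligonucleotide ASO1, and treated with both (VPA+ASO1). VPA inhibits histone deacetylases, and ASO1 is the splicing-correcting oligonucleotide of a study on spinal muscular atrophy, a disease of the SMN1 gene in which splicing of its near-copy SMN2 is the target. The libraries held 21510444 (untreated replicate 1) to 60614968 counts (ASO1 replicate 1), and the other 10 held 39751454 to 48153252. Values are CPM scaled by TMM factors, and changes are log2 fold changes ± SE from fits of 3 libraries per group.

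Libraries with the same replicate number mostly resembled each other across groups, replicate 1 most clearly. Deviations from the group means correlated at r = 0.19 to 0.87 across genes in all 18 pairs of libraries with the same number, genes not being independent replicates. Pairs with different numbers had r = -0.72 to 0.53, the highest for VPA replicate 3 with VPA+ASO1 replicate 2, and every positive value among them was between replicates 2 and 3. The first principal component held 53.8% of the variance and placed replicates 2 and 3 of VPA and VPA+ASO1 between 105.2 and 123.3. The other 8 libraries, VPA replicate 1 (-63.9) and VPA+ASO1 replicate 1 (-55.3) included, lay between -87.6 and -34.2. RN7SL1, the RNA of the signal recognition particle, stood at 211 to 288 CPM in the 4 replicate 1 libraries and at 6.9 to 52.2 CPM in the other 8. The edgeR fit without a block called 0 genes in every comparison. The named values below come from the fit with replicate number as a block, a choice made after those counts were seen, and levels are given by replicate number.

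**Figure D1:**
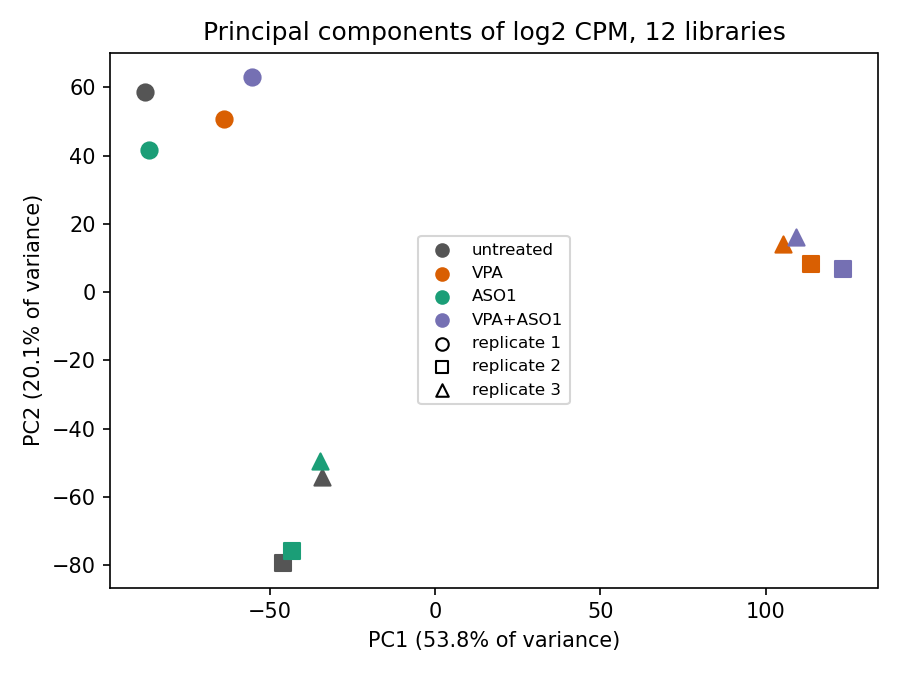
First and second principal components of log2 CPM for the 12 libraries, coloured by group and shaped by replicate number. The 4 replicate 1 libraries lie at 41.7 to 62.9 on the second component, and replicates 2 and 3 of both groups with VPA lie above 105 on the first.

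The comparison of VPA with untreated cells asked what VPA alone changed. MAP2, which encodes a microtubule-associated protein of dendrites (GRCh38 chromosome 2, 209424047 to 209734112), rose by 3.66 ± 0.84 log2 (adjusted p = 0.0422), from 1.14, 0.960 and 1.14 CPM in replicates 1, 2 and 3 to 1.81, 32.0 and 25.9 CPM. COL4A1, a chain of collagen IV, fell by 2.61 ± 0.61 log2 (adjusted p = 0.0428), from 38.8, 48.1 and 48.0 CPM to 20.0, 4.86 and 4.52 CPM. The trypsin inhibitor chain gene ITIH5 (2.71), BMERB1 (2.63), the actin-binding protein gene CORO1A (2.56), the cadherin gene PCDH19 (2.51), the Wnt inhibitor gene DACT3 (2.49) and RGL1 (2.32) also rose, with adjusted p from 0.0101 (BMERB1) to 0.0463 (PCDH19). SYDE1 (-2.42), TRIM71 (-2.39), the HOX gene HOXD11 (-2.34), GIPC3 (-2.34) and KCTD15 (-2.32) also fell, with adjusted p from 0.0379 (HOXD11) to 0.0493 (GIPC3).

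**Figure D2:**
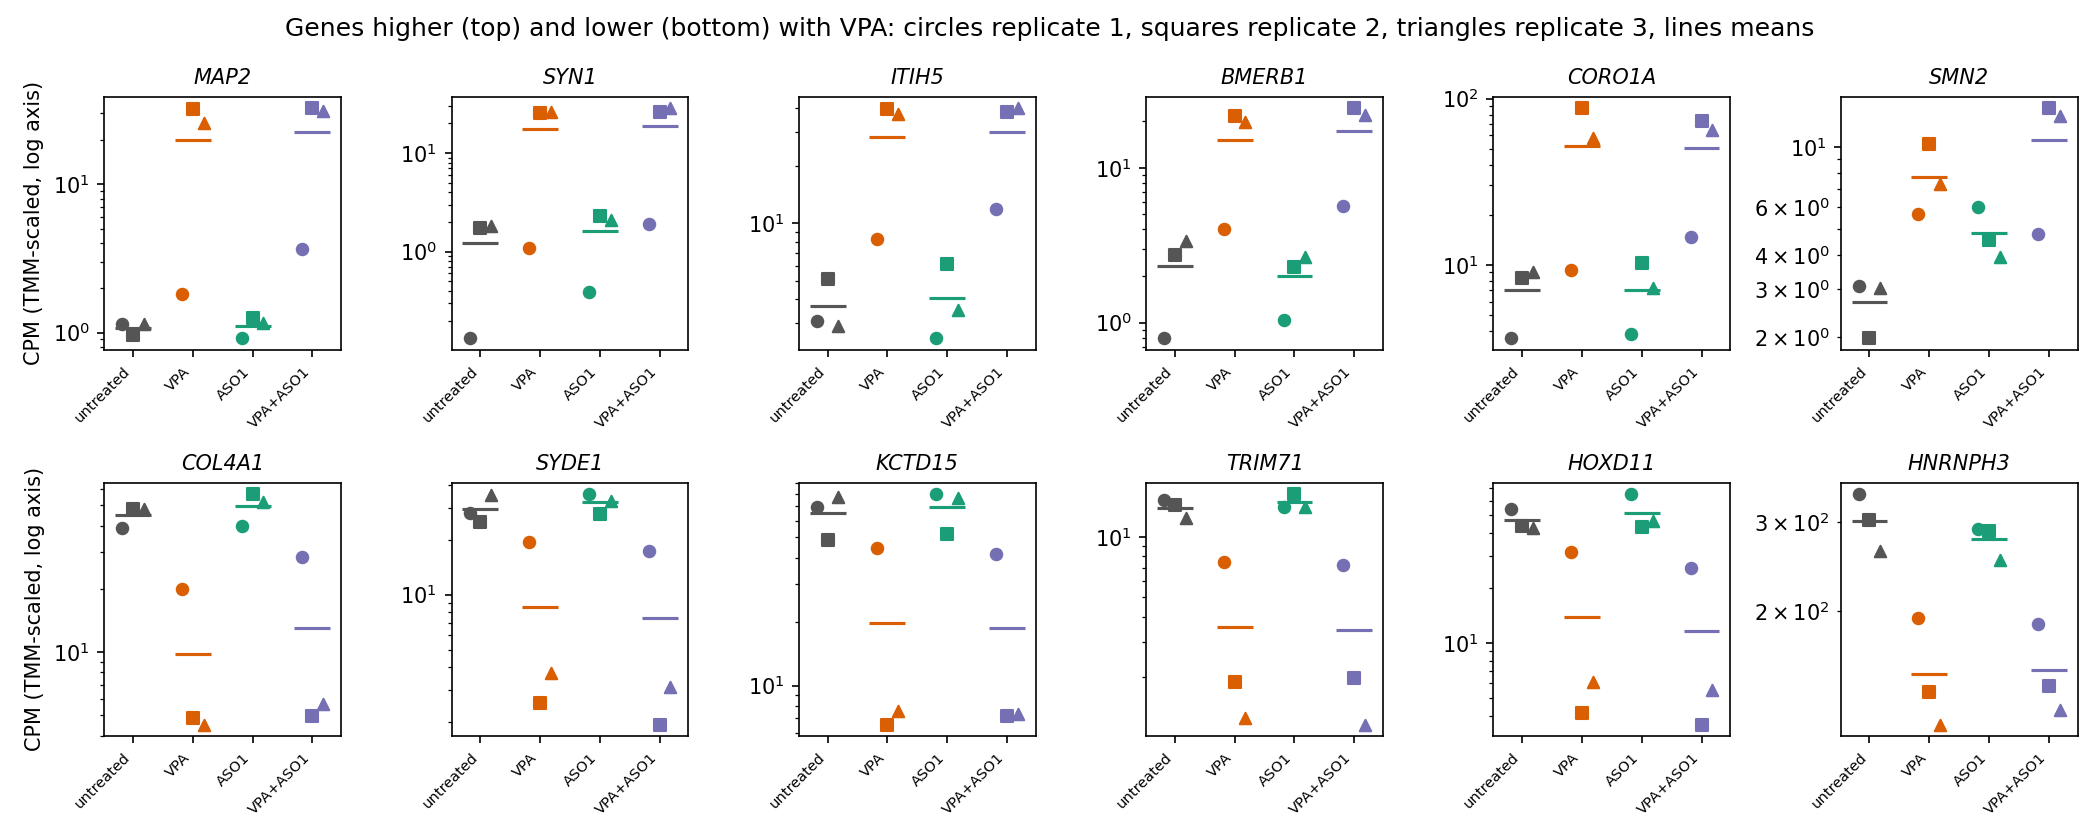
CPM of 12 genes in each library on a log axis, by group, with the mean as a line and the replicate number as the marker shape. MAP2 stood at 1.81 CPM in VPA replicate 1 and at 32.0 and 25.9 CPM in VPA replicates 2 and 3, and HNRNPH3 was lower with VPA in each replicate number.

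Of the 40 neuronal genes tested, 12 rose and none fell, with a median of 1.20 log2. SYN1, a synaptic vesicle protein, rose by 3.65 ± 0.40 log2 (adjusted p = 0.0115), from 0.132, 1.73 and 1.80 CPM to 1.09, 25.4 and 26.2 CPM, and TUBB3, a neuronal tubulin, rose by 1.78 ± 0.23 log2 (adjusted p = 0.0115). The list was higher than other genes by camera (adjusted p = 1.85e-06), and not with an estimated correlation (adjusted p = 0.569). Its median was 0.51, 1.53 and 0.87 log2 in replicates 1, 2 and 3. Of markers of other cell types, 8 blood cell markers, of which CORO1A passed, had medians of 0.32, 0.57 and 0.61 log2, and 9 fibroblast markers, of which none passed, 0.20, -0.68 and -1.03 log2. Neither list was called by camera (adjusted p = 0.173 and 0.564). Of 33 SR and hnRNP splicing factors, 13 fell and none rose (median -0.61 log2; 22 fell when adjusted over the list alone). HNRNPH3 fell by 1.02 ± 0.13 log2 (adjusted p = 0.0115), from 340, 303 and 263 CPM to 194, 138 and 119 CPM, and SRSF7 fell by 0.71 ± 0.13 log2 (adjusted p = 0.0273). That list had camera adjusted p = 4.06e-10 (adjusted p = 0.569 with an estimated correlation) and medians of -0.38, -0.69 and -0.66 log2 in replicates 1, 2 and 3.

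Of 27 genes of glycolysis and hypoxia 4 fell (median -0.84 log2, camera adjusted p = 1.37e-07, adjusted p = 0.877 with an estimated correlation), among them VEGFA, a growth factor of vessels (-1.37 ± 0.30 log2), and PKM, pyruvate kinase (-0.85 ± 0.19 log2). The median was -0.09 in replicate 1 and -1.32 and -0.97 in replicates 2 and 3. All 74 ribosomal protein genes but 1 had a negative value, yet none passed on its own (median -0.38 log2, camera adjusted p = 4.4e-07, adjusted p = 0.903 with an estimated correlation). Their median was 0.22 in replicate 1 and -0.89 and -0.50 in replicates 2 and 3. In the replication and S phase list 7 of 34 fell, MCM7 (-0.94 ± 0.20) and MCM3 (-0.60 ± 0.14), 2 subunits of the replicative helicase, among them (camera adjusted p = 0.0132, 0.569 with an estimated correlation). In fatty acid synthesis 3 of 15 fell, among them the desaturases SCD (-1.44 ± 0.25) and FADS1 (-1.18 ± 0.28), with camera adjusted p = 0.0196 (0.877 with an estimated correlation). In the unfolded protein response 3 of 20 rose, among them HERPUD1 (1.07 ± 0.18) and SYVN1 (0.70 ± 0.12), both of the degradation of proteins from the endoplasmic reticulum (camera adjusted p = 0.00622, 0.877 with an estimated correlation). In TGF-beta and extracellular matrix 3 of 26 fell, COL4A1 and COL4A2 (-2.06 ± 0.45) among them, and ID1 (0.94 ± 0.24) rose (camera adjusted p = 0.0316, 0.903 with an estimated correlation). Mitochondrially encoded mRNAs (2 of 13 fell, MT-ND4 at -0.69 ± 0.17 and MT-ND4L at -0.79 ± 0.21), nuclear genes of oxidative phosphorylation (0 of 41) and Sm proteins (0 of 19) were the other lists called by camera, with adjusted p of 0.0136, 0.00535 and 0.0486, and of 0.877, 0.903 and 0.903 with an estimated correlation. In replicate 1 the medians of oxidative phosphorylation (0.19), Sm proteins (0.12) and TGF-beta and extracellular matrix (0.20) were above 0, opposite to replicates 2 and 3 (-0.66 and -0.38, -0.61 and -0.26, -0.76 and -0.59). The mitochondrially encoded mRNAs stood at -0.60, 0.01 and -0.55. By fry, which does not compare a list with other genes, 5 lists passed in the blocked fit. The neuronal genes and the splicing factors were among them (fry adjusted p = 0.0107 for both).

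Genes that histone deacetylase inhibitors are known to induce did not move as a list: 4 of 24 rose, TUBB3 and the synaptotagmin gene SYT11 (2.26 ± 0.50 log2) among them, and none fell (median 0.13 log2, camera adjusted p = 0.564). The replicate pairs differed in sign, with medians of 0.44, -0.13 and -0.35 log2 in replicates 1, 2 and 3. With ASO1 in both groups they were 0.10, 0.09 and -0.24 log2. Of 10 variant and polyadenylated histone genes, H1-10 (0.86 ± 0.22) rose and H2AZ1 (-0.81 ± 0.21) and MACROH2A2 (-1.53 ± 0.38) fell.

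**Figure D3:**
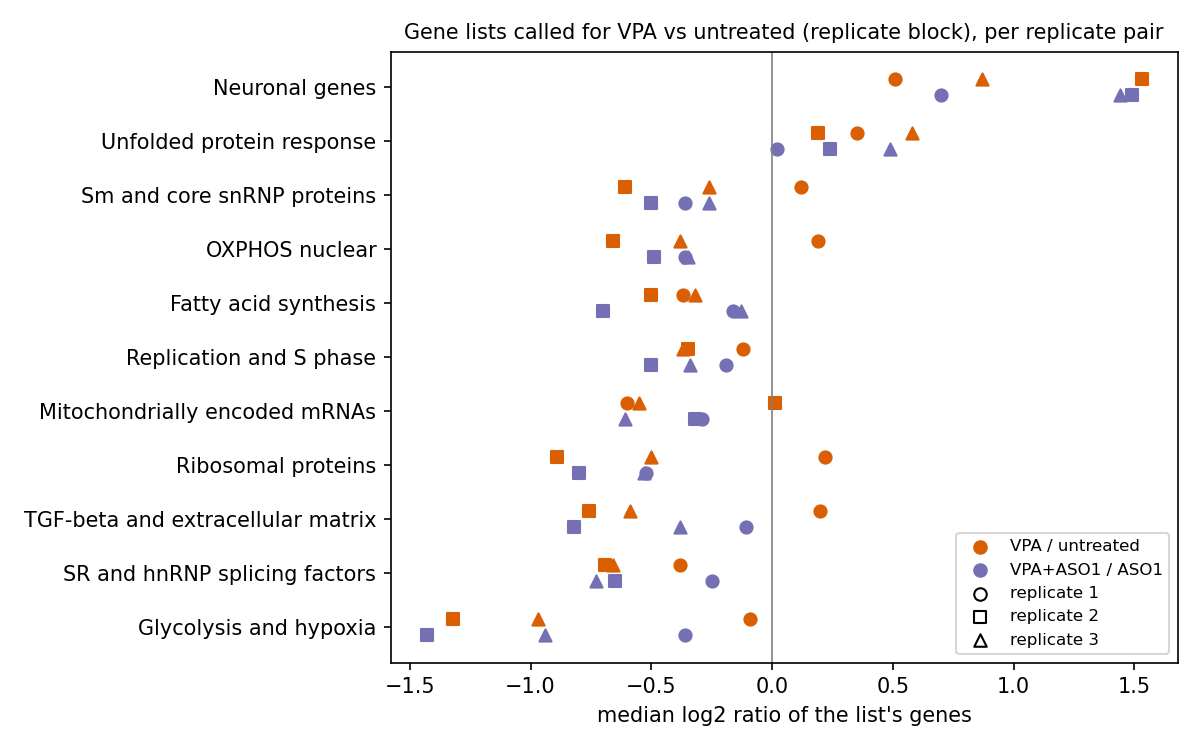
Median log2 ratio of each gene list called by camera for VPA against untreated in the blocked fit, for each replicate pair with and without ASO1. Ribosomal proteins stood at 0.22 log2 in the replicate 1 pair without ASO1 and at -0.89 and -0.50 in replicates 2 and 3.

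SMN2 (chromosome 5, 70049523 to 70090528) and SMN1 (70924941 to 70966375) share nearly all of their sequence, so the split of reads between them and further near-identical copies is uncertain. SMN2 was measured at 3.08, 1.97 and 3.02 CPM in untreated replicates 1, 2 and 3 and at 5.67, 10.2 and 7.30 CPM with VPA (1.48 ± 0.42 log2, adjusted p = 0.0565; 1.78 ± 0.31 and 0.0026 without replicate 1). SMN1 was at 4.79, 4.09 and 3.09 CPM and at 7.78, 2.81 and 3.72 CPM (0.18 ± 0.30 log2, adjusted p = 0.677). Of the 10 genes of the SMN complex list, GEMIN4 fell (-0.85 ± 0.18 log2, adjusted p = 0.0353) and none rose. The list as a whole did not fall and was not called by camera. Its medians were 0.12, 0.35 and 0.36 log2 in replicates 1, 2 and 3 without ASO1 and -0.03, 0.45 and 0.41 with it.

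For VPA against untreated, the edgeR fit without a block called 0 of 21484 genes (smallest adjusted p = 0.217), with 3950 at an unadjusted p under 0.05 where chance gives 1074. DESeq2 called 913 genes (581 higher, 332 lower) and limma voom 0. The edgeR fit with the replicate block called 1499 (799 higher, 700 lower), of which 1012 had changed at least 2-fold. Without replicate 1, a choice made after its libraries were seen to stand apart, 8264 genes were called (4036 higher, 4228 lower), 1441 of them also in the blocked fit and in the same direction. Without VPA replicate 1 alone, 2776 were called with no block. With no filter on low counts the unblocked test called 1 gene, VAT1L (5.44 log2, adjusted p = 0.0051), named after its values were seen. It stood at 0.2, 0 and 0.1 CPM in untreated replicates 1, 2 and 3 and at 1.7, 6.3 and 5.9 CPM with VPA.

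VPA changed genes far less in replicate 1 than in replicates 2 and 3. In a fit of all 12 libraries with a VPA effect of its own in replicate 1, chosen after the data were seen, pairs with and without ASO1 serve as replicates of each other, since replicate 1 has 1 pair of each. The log2 ratios of these 2 replicate 1 pairs correlated at r = 0.28 across the 11064 genes with mean log2 CPM of at least 3. The pair without ASO1 correlated with the ratios of VPA to untreated in replicates 2 and 3 at r = 0.07 and 0.23. For the pair with ASO1 and the ratios of VPA+ASO1 to ASO1 the values were 0.49 and 0.60, so the pooled values below join unlike pairs. In this fit 14015 genes were called in replicates 2 and 3 and 762 in replicate 1, where 506 were higher and 256 lower. Of these, 656 were called in both, 588 of them in the same direction, where 497 shared calls would be had from independent lists. Replicate 1 has fewer pairs than replicates 2 and 3 together, so the counts of 762 and 14015 differ in power as well. The difference between both effects was itself called in 8438 genes. Replicate 1 is a single replicate number, so these counts do not tell how the VPA effect varies between replicate numbers in general. Among the 2986 genes with average log2 CPM of at least 3 that changed at least 2-fold in replicates 2 and 3, 79.9% moved the same way in replicate 1, and the median ratio of the log2 changes was 0.14 (quartiles 0.03 and 0.26).

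**Figure D4:**
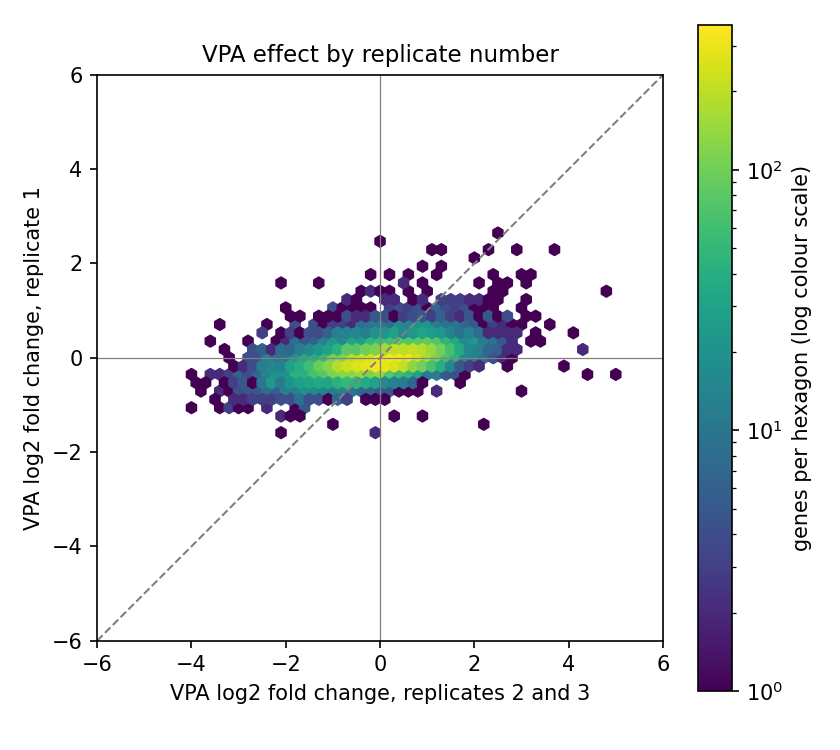
VPA log2 fold change in replicate 1 against that in replicates 2 and 3 for genes with average log2 CPM of at least 3, as a density of genes; the dashed line marks equal changes. The cloud is flatter than the line, with a slope of 0.15 and r = 0.46 across genes.

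The comparison of VPA+ASO1 with untreated cells asked what the combination changed. The neuronal genes MAP2 (3.91 ± 0.84 log2, adjusted p = 0.0319) and SYN1 (3.91 ± 0.40, adjusted p = 0.00685) rose most among the genes named by rule, and BMERB1 (2.89), ITIH5 (2.86), PCDH19 (2.68), CORO1A (2.66) and DACT3 (2.64) followed. MAP2 stood at 3.64, 32.6 and 31.2 CPM in replicates 1, 2 and 3. LRRC75B (-2.83 ± 0.85, adjusted p = 0.0497), SYDE1 (-2.66), the HOX genes HOXA4 (-2.65) and HOXD11 (-2.57), the neural RNA-binding protein gene MSI1 (-2.55) and the cartilage collagen gene COL2A1 (-2.53) fell. CELSR1P1 (-2.81) fell as well, but it is a pseudogene and the origin of its reads is uncertain. SMN2 rose by 1.91 ± 0.43 log2 (adjusted p = 0.0348), to 4.80, 13.9 and 13 CPM, while SMN1 had -0.18 ± 0.30 log2 (adjusted p = 0.667).

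By group, 17 of the 40 neuronal genes rose and none fell (median 1.15 log2, camera adjusted p = 2e-06, adjusted p = 0.41 with an estimated correlation). Of 33 splicing factors 18 fell and none rose (median -0.62, adjusted p = 4.21e-10, 0.54 with an estimated correlation), HNRNPH3 (-0.99 ± 0.13) and SRSF7 (-0.83 ± 0.13) among them. Of 74 ribosomal protein genes 12 fell, 62 when adjusted over the list alone (median -0.58, adjusted p = 1.52e-14, 0.852 with an estimated correlation), among them RPS23 (-0.75 ± 0.18) and RPL6 (-0.65 ± 0.17). Of 27 genes of glycolysis and hypoxia 10 fell (median -0.92, adjusted p = 2.1e-08, 0.852 with an estimated correlation), VEGFA (-1.36 ± 0.30) and PKM (-0.83 ± 0.19) among them. Of 41 genes of oxidative phosphorylation 9 fell, among them NDUFS3 (-0.71 ± 0.16) and NDUFV2 (-0.74 ± 0.17) of complex I (adjusted p = 5.35e-06, 0.852 with an estimated correlation). Of 19 Sm and core snRNP proteins 5 fell, SNRPF (-0.99 ± 0.25) and SNRPE (-1.08 ± 0.28) among them (adjusted p = 0.00109, 0.852 with an estimated correlation), and of 34 replication genes 10 fell, with TYMS, thymidylate synthase, at -1.90 ± 0.43 (adjusted p = 0.00719, 0.54 with an estimated correlation). HERPUD1 (0.81 ± 0.18) and SYVN1 (0.69 ± 0.12) rose again, and the chaperone genes HSPD1 (-0.68 ± 0.17) and HSP90AA1 (-1.13 ± 0.31) fell.

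For VPA+ASO1 against untreated, the edgeR fit without a block called 0 genes (4687 at an unadjusted p under 0.05), DESeq2 1673 (998 higher, 675 lower) and limma voom 0. The blocked fit called 3281 (1763 higher, 1518 lower) and the fit without replicate 1 called 8705 (4268 higher, 4437 lower), 3069 of them in both and in the same direction. With no block, 3483 genes were called without VPA+ASO1 replicate 1 and 6 without VPA+ASO1 replicate 2, the latter gene IDs with equal values.

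The comparison of VPA+ASO1 with ASO1 asked what VPA changed in cells that had ASO1. MAP2 (3.84 ± 0.81 log2, adjusted p = 0.0293), BMERB1 (2.94 ± 0.27), ITIH5 (2.81 ± 0.39) and CORO1A (2.62 ± 0.36) rose, and LRRC75B (-2.82 ± 0.84), SYDE1 (-2.73 ± 0.63) and the glycosyltransferase gene MGAT3 (-2.73 ± 0.72, adjusted p = 0.0408) fell, as did the pseudogene CELSR1P1 (-2.90 ± 0.81), whose reads are uncertain. Of 40 neuronal genes 19 rose and 1 fell (median 1.32 log2, camera adjusted p = 1.76e-06, adjusted p = 0.204 with an estimated correlation), and of 33 splicing factors 14 fell (median -0.63, adjusted p = 6.28e-08, 0.551 with an estimated correlation). Ribosomal protein genes were lower in each replicate pair here, by -0.52, -0.80 and -0.53 log2, and 18 of 74 fell (adjusted p = 1.23e-15, 0.844 with an estimated correlation). SMN2 had 1.06 ± 0.42 log2 (adjusted p = 0.0903) and SMN1 0.03 ± 0.30 log2 (adjusted p = 0.954).

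For VPA+ASO1 against ASO1, the unblocked edgeR fit called 0 genes (4808 at an unadjusted p under 0.05), DESeq2 1889 (1106 higher, 783 lower), and limma voom 0. The blocked fit called 3287 (1648 higher, 1639 lower) and the fit without replicate 1 8341 (4121 higher, 4220 lower). With no block, 3734 were called without VPA+ASO1 replicate 1 and 6 without VPA+ASO1 replicate 2, the latter gene IDs with equal values. With no filter on low counts the unblocked test called 9 genes, 6 higher and 3 lower, among them VAT1L (5.43 log2, adjusted p = 0.00343), HOXB9 (-2.00 log2, adjusted p = 0.0467) and the forkhead factor gene FOXC1 (-1.74 log2, adjusted p = 0.0457), named after their values were seen. HOXB9 stood at 170, 289 and 348 CPM with ASO1 and at 81.2, 44.5 and 75.9 CPM with VPA+ASO1. Averaged over cells with and without ASO1, 6 libraries against 6, the unblocked edgeR test of VPA called 4295 genes (2606 higher, 1689 lower), from 56 to 7818 when each library was left out in turn. That test takes the 6 as independent, though libraries with the same replicate number resembled each other. The count was 9780 with the replicate block (5129 higher, 4651 lower), 11860 without replicate 1 and 6550 by DESeq2. The block takes out a level shared by a replicate number, not a VPA effect that differs between numbers. Deviations of VPA and VPA+ASO1 libraries with the same number correlated at r = 0.87, 0.65 and 0.64 in replicates 1, 2 and 3. Those of untreated and VPA libraries did so at 0.40, 0.19 and 0.33. All of these counts thus treat VPA and VPA+ASO1 libraries of one number as independent.

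The comparison of ASO1 with untreated cells asked what ASO1 alone changed. SMN2 was measured at 5.99, 4.53 and 3.93 CPM in ASO1 replicates 1, 2 and 3, higher than in untreated cells in 3 of 3 replicate pairs, but the difference did not pass (0.85 ± 0.42 log2, adjusted p = 1). SMN1 stood at 3.92, 3.87 and 2.52 CPM (-0.21 ± 0.30 log2, adjusted p = 1). No gene was called by edgeR without a block (69 at an unadjusted p under 0.05), with it (153) or without replicate 1 (197), and none by DESeq2 (69) or limma voom (52). All of these lie far under the 1074 that chance gives, so these counts of 0 say little. With a replicate effect of its own in cells with and without VPA, 0 genes were called (579 at an unadjusted p under 0.05, where chance gives 1074). Averaged over cells with and without VPA, ASO1 changed 0 genes with and without the block, 2 by DESeq2, and 1 without replicate 1 (PANK4, -2.03 log2, adjusted p = 0.0185). None of the 39 gene lists was called in the fits with and without a block. Without replicate 1, ribosomal proteins (median -0.12 log2, adjusted p = 0.0162, 0.945 with an estimated correlation) and oxidative phosphorylation (median -0.11, adjusted p = 0.0233, 0.945 with an estimated correlation) were lower, with no member passing.

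The comparison of VPA+ASO1 with VPA asked what ASO1 changed in cells that had VPA. PANK4, a relative of the pantothenate kinases of coenzyme A synthesis, was lower in 3 of 3 replicate pairs, at 21.7, 18.1 and 25.4 CPM with VPA and 9.63, 2.04 and 1.75 CPM with VPA+ASO1 (-2.28 ± 0.65 log2 with no block, adjusted p = 1). It was the 1 gene called without replicate 1 (-3.53 ± 0.25 log2, adjusted p = 0.00599), was chosen after its values were seen, and stood at 9.23, 37.1 and 34.7 CPM in untreated cells. SMN2 had 0.43 ± 0.40 log2 and SMN1 -0.37 ± 0.30 log2 (adjusted p = 1 for both). The edgeR fit called 0 genes without a block (52 at an unadjusted p under 0.05) and with it (126), where chance gives 1074. Limma voom called 0, and DESeq2 1, a gene ID with no symbol in the gene names used. Without a block, ribosomal proteins were lower by a median of -0.21 log2 (camera adjusted p = 4.8e-22, 0.993 with an estimated correlation) and replication-dependent histones by -0.46 (adjusted p = 2.96e-10, 0.67 with an estimated correlation), with no member passing. Oxidative phosphorylation (-0.15) and Sm proteins (-0.14) were also called, with adjusted p = 0.993 for both with an estimated correlation. The blocked fit called 6 lists, these 4, immediate early genes (-0.11) and abundant structural noncoding RNAs (-0.29), and 0 with an estimated correlation. Without replicate 1 the histone list alone was called (median -0.34, adjusted p = 0.034, 0.974 with an estimated correlation).

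The interaction asked whether the effects of VPA and ASO1 added up on the log scale. No gene passed: edgeR called 0 without a block (54 at an unadjusted p under 0.05), with it (134) and without replicate 1 (221), and DESeq2 (54) and limma voom (50) called 0. Chance gives 1074 at that unadjusted p, so these counts of 0 say little as well. Named by rule as those with the smallest p, NAPRT, an enzyme of NAD synthesis (-1.52 ± 0.59 log2), PANK4 (-2.26 ± 0.89) and FKBPL (5.95 ± 2.96) had adjusted p = 1. FKBPL was at 0 CPM in 3 of the 4 replicate 1 libraries and ranged from 0.0741 to 39.1 CPM in the others, so its fold change rests on few counts in some groups. Camera called 4 lists without a block, all lower: ribosomal proteins (median -0.19 log2), replication-dependent histones (-0.36), oxidative phosphorylation (-0.14) and Sm proteins (-0.11). It called 5 with the block, 0 without replicate 1 and 0 with an estimated correlation. The VPA effects with and without ASO1, which share no library, correlated across 21484 genes at r = 0.84 (Spearman 0.87). Over the genes with average log2 CPM of at least 3, r was 0.97, with a slope of 1.04. Both effects share replicate numbers, so their agreement is not independent. By pair, VPA ratios with and without ASO1 correlated at r = 0.28, 0.96 and 0.98 within replicates 1, 2 and 3. Between replicates 2 and 3 the values were 0.87 and 0.89, and between replicate 1 and the others 0.17 to 0.59. Of the 3446 genes called in either blocked comparison, 99.7% had the same sign in both. The ASO1 effects with and without VPA correlated at r = 0.08 (Spearman 0.06), and the main effects of VPA and ASO1 at r = 0.09 (Spearman 0.14), where leaving out VPA replicate 1 gave -0.45 and leaving out VPA+ASO1 replicate 1 gave 0.55.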

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

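The tests of the smaller response in replicate 1 (thinning, swapped labels and a fixed share of cells), the ASO1 intervals, the permutations of gene counts, and the fits with a VPA effect of its own in replicate 1 or a replicate effect of its own in cells with and without VPA were chosen after the results they concern were seen; the permutations of gene lists were not.

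The effect of VPA differed between replicate numbers: the interaction term of VPA with replicate 1 was called in 8438 genes. The change in replicate 1 was smaller in 4785 of them and larger or opposite in 3653. That fit takes pairs with and without ASO1 of one number as replicates, and replicate 1 is a single number. The SD of the log2 ratios with over without VPA was 0.41 (no ASO1) and 0.37 (with ASO1) in replicate 1 and 0.92 to 1.06 in replicates 2 and 3. Lower depth is argued against in the pair with ASO1, whose replicate 1 libraries hold more counts together (103707365) than those of replicate 2 (86408055) or 3 (82423596), while the SDs of replicates 2 and 3 were at least 2.49 times that of replicate 1. In the pair without ASO1, thinning every library to the total of untreated replicate 1 left all SDs as they were to 2 decimals. At equal totals they were 0.41 in replicate 1 and 1.04 and 0.92 in replicates 2 and 3 (lower ratio 2.24). For the 11332 genes covered, this argues against lower depth in that pair as well. Swapped labels within replicate 1 are argued against, since 65.3% and 88.8% of the genes changed at least 2-fold in replicates 2 and 3 of the other pair moved the same way. A fixed share of cells without a response could not be decided. It would give risen and fallen genes the same share of their linear change, if the scaling is right and replicate 1 started from the same levels. The medians were 0.044 and 0.177 without ASO1 and 0.135 and 0.355 with it, and differed by at least 0.062 under 3 scalings. Without ASO1 the difference moved from 0.134 with TMM factors to 0.062 with upper-quartile factors. Untreated replicate 1 also lay apart on the second principal component (58.7, against -79.4 and -54.2 in replicates 2 and 3). A weaker or shorter treatment in replicate 1 may remain an explanation; no dose or time is given per library, so it cannot be told apart from a batch that shares the replicate number, and no biological explanation was tested.

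No gene was called for ASO1 against untreated. Spread between replicates could hide changes, but in the fit with a replicate effect of its own in cells with and without VPA, 99.2% of 11332 genes with average log2 CPM of at least 3 had a 95% interval of the ASO1 effect inside -1 to 1 log2 (median half-width 0.23). The share was 93.7% with the replicate block and 79.4% without it. This argues against hidden 2-fold changes in most expressed genes, and leaves smaller changes, changes in scarce genes and changes in splicing, which gene counts do not show, open.

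With labels permuted, the 10 splits of 3 libraries against 3 are too few for a share under 0.05. The real count was 0 genes in each of the 5 unblocked comparisons, which all 10 splits must reach, and the highest of the other splits was 1 for ASO1 against untreated and 0 in the other comparisons. In the blocked fits, 1 of 4 within-number swaps, the real one, gave the real counts of 1499, 3281 and 3287 genes for VPA against untreated, VPA+ASO1 against untreated and VPA+ASO1 against ASO1, and the highest of the others was 0; all 4 gave 0 for both ASO1 comparisons. These too are too few for a share under 0.05. For the interaction the real count was also 0, which all 100 draws must reach, so they decide nothing; the highest was 7834, in draws that mix replicate numbers. For gene lists, 8 of 10 splits gave at least the real 9 lists for VPA against untreated (highest other 18), 8 of 10 the real 7 for VPA+ASO1 against untreated (highest other 17), and all 10 the real 0 for ASO1 (highest other 16). The splits with most lists mix replicate numbers, but those that keep the numbers balanced also gave up to 10 lists for VPA, 15 for VPA+ASO1 (untreated and VPA+ASO1 replicate 3 exchanged) and 3 for ASO1. Each of the other splits still keeps part of the real contrast, so lists called in them need not be false calls.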

How the results depend on the processing

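Values with replicate 1 left out, with a replicate effect of its own in cells with and without VPA, and with the block joined to another scaling or to the 2-fold requirement were chosen after the data were seen. Counts of 0 to which the text compares are those of the unblocked edgeR test, and the cause of a change was not tested unless given. In the order VPA against untreated, VPA+ASO1 against untreated and VPA+ASO1 against ASO1, the genes called were 1, 1 and 9 with no filter; 913, 1673 and 1889 by DESeq2; 1499, 3281 and 3287 with the replicate block; 1527, 3362 and 3376 with the block and DESeq2-type factors; 1161, 2972 and 2987 with the block and upper-quartile factors; 1012, 2042 and 2042 with the block and at least 2-fold; 8264, 8705 and 8341 without replicate 1; 5495, 5848 and 5576 without it and at least 2-fold; and 10226, 10615 and 10329 without it and with the block. With each library left out they ranged from 0 to 2776, 0 to 3483 and 0 to 3734, the highest without replicate 1 of the group with VPA in each case, and 6 genes were called without VPA+ASO1 replicate 2 in either comparison of VPA+ASO1. These 6 are gene IDs with no symbol at under 1.5 CPM. They have equal rounded CPM in each library and equal log2 fold changes, so they may not be separate measurements. In the blocked fit the share of higher genes moved with the scaling: for VPA+ASO1 against ASO1, 1551 were higher and 1825 lower with DESeq2-type factors, 1549 and 1438 with upper-quartile factors. For VPA+ASO1 against VPA, 1 gene was called by DESeq2, 1 without replicate 1, also at least 2-fold and with the block (PANK4), and 1 with a replicate effect of its own in cells with and without VPA, a gene ID with no symbol. Other settings, limma voom included, called 0, and ASO1 against untreated and the interaction stayed at 0 in every setting run. Without the block, camera at the preset correlation called 9 lists for VPA and 7 for VPA+ASO1 against untreated. With an estimated correlation it called 0, and fry without the block called 0 for both. With the block, fry on all 12 libraries called 5 for VPA and 4 for VPA+ASO1. Without replicate 1, fry called 11 and 12. Camera at the preset correlation called 11 for VPA+ASO1 without replicate 1 and 12 without it and with the block. For ASO1, camera called 1 with the stricter filter and 2 without replicate 1, with or without the block. With each library left out, lists ranged from 5 (without untreated replicate 2) to 11 for VPA, from 7 to 11 (without untreated replicate 1 or 3) for VPA+ASO1 and from 6 to 9 for ASO1, where every omission leaves replicate numbers unbalanced. The correlation of the VPA effects moved from 0.84 to 0.34 with no filter, which adds genes with few counts, and to 0.92 with the stricter filter, and ranged from 0.74 to 0.82 with a library left out and was 0.83 without replicate 1. That of the ASO1 effects moved from 0.08 to -0.01 with no filter, 0.14 with the stricter filter, 0.02 by limma voom and 0.02 without replicate 1 and with the block, and ranged from 0.01 to 0.08; that of the main effects ranged from -0.45 (without VPA replicate 1) to 0.55 (without VPA+ASO1 replicate 1). Of 1727 alternative values of named genes, 1228 kept their side of the threshold and 499 passed it where the unblocked test had not. None passed with the opposite sign, and 13 values that did not pass changed sign. Most of these genes were named because the blocked fit called them. That fit gave 79 of the 499, and the block with DESeq2-type and upper-quartile factors 79 and 66, so those passes were largely fixed by the choice. Less can be said of scarce genes: of all 21484 genes, 73.5% had an ASO1 interval inside -1 to 1 log2, against 99.2% of the expressed ones. Whether depth or spread between replicates widened the intervals of scarce genes was not tested.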

Other observations

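The gene families and the tests of this part were chosen after the data were seen; the bound for gene span was set before its values were computed, and the genes of the abundance test were chosen again after a first result was seen.

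Of 11 HOXA genes tested, 7 fell and none rose in VPA against untreated in the blocked fit (median -1.31 log2, camera adjusted p = 3.26e-06 over 297 families), of 9 HOXB genes 6 fell (median -1.64, adjusted p = 4.63e-05) and of 9 HOXC genes 4 fell (median -1.19, adjusted p = 0.0375). With an estimated correlation none of these families passed (adjusted p = 0.848 for each). The HOXA medians were -0.68, -1.56 and -1.68 log2 in replicates 1, 2 and 3 without ASO1 and -1.02, -1.70 and -1.93 with it. In VPA+ASO1 against untreated, 8 of the HOXA and 8 of the HOXB genes fell. Of 8 HOXD genes 4 fell, and that family did not pass (median -1.10, adjusted p = 0.107).

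Of 40 CFAP genes, which encode proteins of cilia and flagella, 8 rose and none fell in VPA against untreated (median 0.74 log2, adjusted p = 3.02e-05), and 10 rose and 1 fell in VPA+ASO1 against untreated. Of 11 DNAAF genes, of the assembly of dynein arms, 2 rose (median 1.95, adjusted p = 0.00479) and 6 rose with VPA+ASO1; the medians were 0.36, 2.21 and 2.04 log2 in replicates 1, 2 and 3. The 16 IFT genes, of transport along the cilium, had a median of 0.59 (adjusted p = 0.00479) with none passing, and the 500 ZNF genes a median of 0.42 with 8 higher and 14 lower (adjusted p = 0.00953). In replicate 1 without ASO1 the medians were near 0 for IFT (0.01, against 0.97 and 0.90 in replicates 2 and 3) and ZNF (-0.05, against 0.77 and 0.45). With an estimated correlation each of these families had adjusted p = 0.848. The SRSF genes (median -0.61) and the RPL genes with their pseudogenes (median -0.39, 0.24 in replicate 1) were the other families called in all 3 comparisons of cells with and without VPA. The 9 families kept their direction with DESeq2-type and upper-quartile factors and without replicate 1, and with an estimated correlation none of the 297 passed (smallest adjusted p = 0.848 for VPA against untreated).

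Whether abundant transcripts fell with VPA while scarce ones rose could not be decided. With genes and their abundance taken from libraries outside each comparison (mean log2 CPM of at least 3), the log2 change in replicates 2 and 3 correlated with abundance at Spearman's rho = -0.13 without ASO1 (11145 genes) and -0.12 with it (11107 genes), close to a bound of -0.1. The medians of the 20% highest genes were -0.29 log2 in both, and those of the 20% lowest 0.03 and 0.01. So the lowest of these genes did not rise as a whole, and scarcer genes were left out. The result moved with the choice of genes. At first they were chosen by average log2 CPM of at least 3 over all libraries, the compared ones included (11332 genes). The medians of the 20% lowest were then 0.38 and 0.36 log2, with rho = -0.24 and -0.23. Counts give relative levels, so a change in total RNA per cell stays open. A second hypothesis, that long genes rose more than short ones, could not be decided: rho with gene span was 0.17 and 0.10 against a bound of 0.1 set beforehand, over the 94.6% of genes with a span, and in replicate 1 it was -0.38 and 0.28.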
